A study of Rattus norvegicus with 6 samples.

How the data were processed

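The series measured RNA in lung tissue of 6 rats on 6 Agilent arrays, 3 from saline-treated and 3 from silica-treated rats. Groups and replicate numbers were taken from the sample titles, and the series design states separate animals. Per the labels' protocols, total RNA was labelled with Cy3 for a 1-colour hybridisation. Agilent Feature Extraction 10.7.1.1 is named in the submitters' processing notes. The background correction, the filter on probes, the software that normalized and the array's slide and scan date are not given in the sources used here.

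The deposited table gives 1 value for each of 51323 probe IDs on each array, on a log scale taken here as log2. The authors' values run from 1.59 to 18.0 with a median of 5.43 on each array and no missing values. The log base is not stated. Read as log2 they span 4.94 powers of 10, and read as natural logs 7.13, which is more than a scanner covers. The sorted values of the 6 arrays differ by at most 0.00165, so the deposited log2 values are taken as quantile normalized between arrays with the control spots included. They were not centred per probe. Higher values mean brighter spots, since the bright-corner control lies near the top of the scale and the hairpin and dark-corner controls near its floor. Quantile normalization makes the distribution of the arrays equal, so a change of most probes in one direction would not be visible, and other scalings of this table that use all probes move it little.

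The 68 control rows (spike-in, corner, hairpin, ERCC, ETG and human, mouse and rat GAPDH and PGK1 probes) were left out of the main test, and 51255 probes were tested. No probe was removed for low signal, since no detection calls were used. The mean log2 values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 silica against 3 saline arrays, no covariate, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The control rows were fitted together with all other rows, 51323 in all, and adjusted over them. The dark-corner spot of each array, 2.27 to 3.37, served as the level of background. The hairpin control read lower, 1.68 to 1.80, so statements on background depend on this choice. As no detection limit per spot was used, folds of dim probes are open to background. Endings 3 and 5 of the GAPDH and PGK1 probe IDs were read as nearer the 3' and 5' ends of the transcript, which no label states. Custom and catalogue probes were told apart by the prefix of the ID, a grouping chosen after seeing the data. What the custom probes target is not stated in the sources used here.

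The design fixed before the data were examined held 4 results. Only the probe fit could be run. The gene fit, the count of noncoding probes and the 34 gene lists (cell type markers, matrix, inflammation, metabolism and others) all needed a gene name per probe. The table of 47357 RefSeq genes used here matched 0 of the probe IDs, so none of these was run. The rule for named genes, written for the gene fit, asked for 15 rises and 15 falls plus listed genes, and was applied to probes and shortened. The 2 probes with the largest rise and the 2 with the largest fall were named, among those with an adjusted p under 0.05 and no overlap between the groups.

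The test was checked on simulated data made from the means and variances of the real probes, for silica against saline, with 51255 probes. Among those with a saline mean over 5, 100 were changed by 1 and 100 by 2 on the log2 scale. It recovered 41% of the former and 83% of the latter, and 7 unchanged probes were called. With no probe changed, 0 were called and 5.38% had an unadjusted p under 0.05. Far fewer probes were changed here than were called in the real data, which makes the adjusted threshold stricter. The shares recovered are therefore not those of the real test. Simulated probes were independent and no array carried an offset of its own, so the 0 calls do not give the rate of false calls in the real arrays.

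Alternatives fixed before the data were examined were another quantile normalization, a common median, 2 filters on dim probes, 32 added to the linear value before log2, an intensity trend with a robust prior, array weights, the replicate number as a block, thresholds with a 2-fold minimum, and each array left out in turn. The 6 E1A spike-in probes with a mean over 4.5 gave a further scaling, added after seeing the data. Every column of the table belonged to 1 of the 6 samples.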

Results

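RNA abundance was measured in lung tissue of 6 male rats with 1-colour (Cy3) Agilent arrays, 1 array per rat. Of these, 3 rats had received saline and 3 had received silicon dioxide (silica), each as 1 mL delivered into the lung by intubation, and lungs were taken after 28 days. Silica particles lodged in the lung are a standard way to produce silicosis, a fibrosing lung disease, in rodents. The design thus holds a single comparison, silica against saline, which asks which RNAs, long noncoding RNAs among them, differ in the lung in a rat model of silica-induced fibrosis. Each array gave 51255 probes that were not control spots. Of these, 30418 carry an ID of the manufacturer's catalogue (called catalogue probes here) and 20827 carry a numbered ID that starts with CUST (called custom probes here), with 10 further custom probes in a small series of their own. The IDs were not paired with gene names in the sources used here, so single probes are given by ID. The exceptions are control spots whose IDs name a gene. The precision of the values is limited by the 3 arrays per group. Between 72.2% and 81.5% of the probes lay above the dark-corner control spot of their own array.

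The arrays differed more between the groups than within them. Pearson correlations over probes were 0.972 to 0.985 among the saline arrays, 0.978 to 0.980 among the silica arrays and 0.952 to 0.965 between the groups. The first principal component held 47.5% of the variance and parted all 3 silica arrays (63.8 to 92.8) from all 3 saline arrays (-81.1 to -60.5). The second held 19.9% and set saline replicate 1, at 91.3, apart from saline replicates 2 and 3, at -50.3 and -34.9.

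In the lungs of silica-treated rats, the probes for 2 enzymes of glycolysis gave clearly brighter signals. The glyceraldehyde-3-phosphate dehydrogenase gene (GAPDH in the probe IDs), often used as a reference gene, rose 2.75-fold at one rat probe and 2.83-fold at the other. The phosphoglycerate kinase 1 gene (PGK1) rose 2.29-fold and 2.46-fold at its rat probes. On the log2 scale, Rat-GAPDH_3 went from 12.57 ± 0.21 in saline to 14.03 ± 0.010 in silica (SD, n = 3 rats each). The limma difference was 1.46, with a standard error of 0.12 and a Benjamini-Hochberg adjusted p of 0.00472. Rat-GAPDH_5 went from 10.93 ± 0.17 to 12.43 ± 0.076 (SD, n = 3 each), a difference of 1.498 (limma standard error 0.11, adjusted p = 0.0037). Rat-PGK1_3 went from 8.74 ± 0.19 to 9.94 ± 0.16 (SD, n = 3 each), a difference of 1.19 (limma standard error 0.14, adjusted p = 0.0102). Rat-PGK1_5 went from 7.36 ± 0.16 to 8.66 ± 0.12 (SD, n = 3 each), a difference of 1.30 (limma standard error 0.12, adjusted p = 0.00579). At each of these 4 probes every silica array lay above every saline array. Chance gives such a separation in either direction for 10% of probes, and 38.4% of the tested probes showed it on these arrays. No exact permutation test of 3 against 3 arrays can give a two-sided p below 0.1. The probes were singled out because their IDs name a gene, after their values had been seen. When the arrays were instead aligned on the added E1A spike-in probes, a scaling chosen after seeing the data, the adjusted p of limma was 0.0373 and 0.0388 for the GAPDH probes and 0.119 and 0.0528 for the PGK1 probes, with differences of 1.40, 1.44, 1.14 and 1.24. Over the 15 alternatives in which they were fitted the adjusted p of limma ranged from 0.0016 to 0.0616 for the GAPDH probes and from 0.00195 to 0.119 for the PGK1 probes. Not all of these put the control probes to a test. The 2 filters on dim probes did not apply to their fit, and the further quantile normalization left their values as they were.

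**Figure D1:**
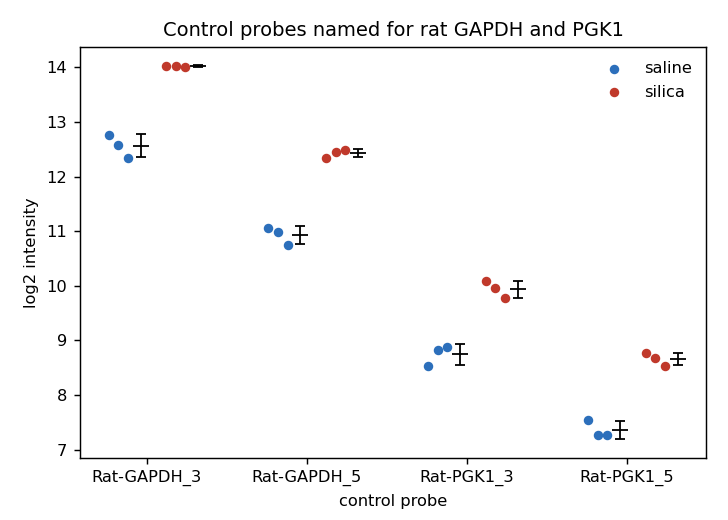
Log2 intensity (y axis) of the 4 control probes named for rat GAPDH and PGK1 (x axis) on each of the 3 saline (blue) and 3 silica (red) arrays; the black marks give the group mean and SD. Every silica array lies above every saline array at each probe, with rises of 2.29-fold to 2.83-fold.

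Across the array, 7391 of 51255 probes (14.4%) changed between silica and saline in limma's moderated test at an adjusted p under 0.05, of which 4028 were higher and 3363 lower in silica. The typical change had a similar size both ways, with a median of 0.87 on the log2 scale for the probes that rose and -0.89 for those that fell. Large changes were mostly rises. At 4-fold or more, 423 probes rose and 95 fell, and at 8-fold or more 120 rose and 3 fell. Among the 26624 probes whose lower group mean was above 5, and so well above the floor of the scale, 204 rose and 19 fell by 4-fold or more. The groups did not overlap at 19682 probes (38.4%, against 10% by chance), and 15637 probes had an unadjusted p under 0.05. The standard error of the log2 difference had a median of 0.18, and the smallest change called was 0.29. In 178 of the 7391 changed probes each group mean lay below the mean dark-corner value of its group, so no fold is given for them.

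The number of changed probes depended on which arrays were included, and fell without any array except saline replicate 1. It was 2766 without saline replicate 2, 1914 without saline replicate 3, 3614 without silica replicate 1, 2274 without silica replicate 2 and 3960 without silica replicate 3, and of these 2573, 1814, 3319, 2070 and 3609 were among the 7391. Without saline replicate 1 it was 8664, of which 5640 were among the 7391. With the arrays aligned on the spike-in probes, 1309 probes passed, and 68.1% of them were higher in silica, against 54.5% as deposited. The share of higher probes was also larger without saline replicate 2 (67.9%), saline replicate 3 (72.6%) or silica replicate 2 (66.8%). Other settings lowered that share, to 51.0% under the stricter filter on dim probes and 51.5% with array weights. At a 2-fold change with an unadjusted p under 0.05 it was 49.4%.

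**Figure D2:**
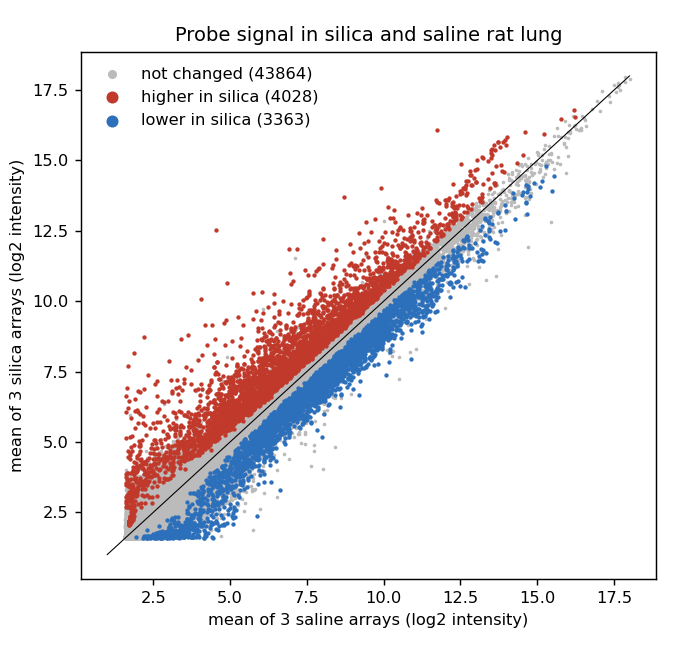
Mean log2 intensity of each of 51255 probes over the 3 silica arrays (y axis) against the mean over the 3 saline arrays (x axis), with the line of equality in black. The 4028 probes higher in silica (red) reach much farther from the line than the 3363 lower in silica (blue), and the remaining probes are grey.

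The largest rise among probes that passed the test with no overlap between the groups was that of catalogue probe A_44_P491796, which went from 4.54 ± 0.92 in saline to 12.53 ± 0.34 in silica (SD, n = 3 each). The difference was 7.998 on the log2 scale, with a standard error of 0.49 and an adjusted p of 0.0027 in limma, and 6.71 with 32 added before log2. Catalogue probe A_44_P309097 rose by 6.55 (standard error 0.28, limma adjusted p = 0.00176), from 2.19 ± 0.52 to 8.73 ± 0.19 (SD, n = 3 each). In saline its mean lay below the mean dark corner of 2.73, and it was above the dark corner of the array on 2 of 3 arrays, by under 0.1, so its saline level is not clearly above background and no fold is given. With 32 added before log2 the difference was 3.64. Catalogue probe A_44_P669819 fell by 3.51 on the log2 scale, from 5.88 ± 0.40 in saline to 2.37 ± 1.21 in silica (SD, n = 3 each, limma standard error 0.64, adjusted p = 0.0273). In silica its mean lay below the mean dark corner of 3.17, and it was above the dark corner of the array on 1 of 3 arrays, so its silica level is not above background and the size of the fall is uncertain, and with 32 added before log2 the difference was -1.25. Catalogue probe A_44_P1090877 fell by 3.34, from 6.64 ± 1.17 to 3.30 ± 0.58 (SD, n = 3 each, limma standard error 0.66, adjusted p = 0.0318). In silica it was above the dark corner on 2 of 3 arrays and its mean was close to the mean dark corner of 3.17, so its silica level is not clearly above background, and the difference was -1.70 with 32 added. Both rises kept an adjusted p under 0.05 in limma without any one array. The fall of A_44_P669819 missed that threshold without saline replicate 2 (adjusted p = 0.0866), saline replicate 3 (0.0979), silica replicate 1 (0.0786) or silica replicate 2 (0.0839), with limma, while the difference stayed at -3.46, -3.33, -3.16 and -3.16. The fall of A_44_P1090877 missed it in limma without saline replicate 3 (adjusted p = 0.0894) or any one silica array (0.092, 0.0878 and 0.0719), with differences of -3.56, -3.01, -3.48 and -3.54. Over the 14 alternatives that tested these 2 falls, which the stricter filter on dim probes left out, the adjusted p ranged from 0.0112 to 0.0979 for the first and from 0.0172 to 0.092 for the second.

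Custom probes changed less often than catalogue probes. Of the 20827 custom probes, 2337 (11.2%) changed, with 1221 higher and 1116 lower in silica. Of the 30418 catalogue probes, 5048 (16.6%) changed, with 2801 higher and 2247 lower. The odds ratio was 1.57 for catalogue over custom probes (95% interval 1.49 to 1.66, Fisher's exact test, two-sided, p = 2.04e-66). This test treats probes as independent, which they are not. Custom probes were also dimmer, with a median log2 intensity of 4.85 against 5.80, and dim probes changed less often in both classes. Under a mean of 3, 3.42% of probes changed, and over a mean of 10, 29.8% did. At the signal distribution of the catalogue probes, 13.0% of custom probes would have changed, which leaves a gap of 3.61 percentage points (95% bootstrap interval over probes 2.94 to 4.25) out of 5.37. Large changes in custom probes also were mostly rises, with 95 higher and 21 lower by 4-fold or more. In the separate series of 10 custom probes, 6 rose and 0 fell in the limma fit, and 8 had an unadjusted p under 0.05. Both shares moved when single arrays were left out. The custom and catalogue shares were 14.5% and 18.5% without saline replicate 1, 4.12% and 6.26% without saline replicate 2, and 2.76% and 4.39% without saline replicate 3. They were 5.37% and 8.19% without silica replicate 1, 3.44% and 5.11% without silica replicate 2, and 5.82% and 9.01% without silica replicate 3.

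**Figure D3:**
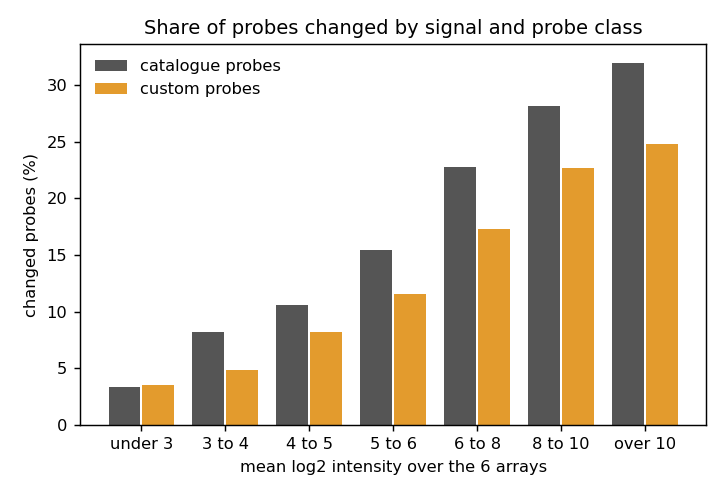
Share of probes that changed between silica and saline (y axis, percent, adjusted p under 0.05) among catalogue (grey) and custom (orange) probes, by the mean log2 intensity of the probe over the 6 arrays (x axis). The share rises with signal in both classes, and custom probes lie below catalogue probes in each class of signal except under 3, where 3.34% of catalogue and 3.52% of custom probes changed.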

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

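All tests of explanations in this part were chosen after the results they address were seen. Only the bounds for a shared background level were set before the value of their own test was seen. The control spots lay outside the main test, and those for GAPDH and PGK1 were brighter in silica in every design, by a mean over the 2 probes of 1.48 for rat, 1.41 for human and 1.14 for mouse GAPDH, and 1.24 for rat, 0.96 for human and 1.29 for mouse PGK1, on the log2 scale. These 12 probes name 2 genes and were all read with rat RNA on the same 6 arrays, so they are not independent measurements. The SDs given next for them and for the spike-ins are over probes and not over rats. A shift in array scaling that was left after the quantile normalization and was as large as this rise is argued against. The 6 bright E1A spike-in probes differed by a median of 0.050 (SD 0.24) between the groups, against 1.28 (SD 0.27) for the 12 probes. Without saline replicate 1 it was 0.29 (SD 0.32) against 1.36 (SD 0.31). Singly the bright E1A probes ran from -0.31 to 0.41, and the dimmer E1A probes left out rose by 0.068 to 0.68. Smaller shifts are therefore not excluded. Less intact RNA in saline as the whole cause would spare the probes nearer the 3' end, yet those ending in 3 rose by 1.12 (SD 0.31) and those ending in 5 by 1.39 (SD 0.13). The probe ending in 5 rose more than its partner in all 6 pairs (ending 3 minus ending 5, silica minus saline, -0.84 to -0.037). The difference was within the spread for rat GAPDH (-0.037, SD 0.056 in saline and 0.084 in silica) and rat PGK1 (-0.11, SD 0.36 and 0.040). The same held for mouse PGK1 (-0.053, SD 0.047 and 0.076). It was larger for human GAPDH (-0.34), human PGK1 (-0.84) and mouse GAPDH (-0.22). A part of the rise at the probes ending in 5 may come from integrity, but the rat pairs do not show it beyond their spread. Other transcripts that share the probe sequence, which the count of 12 rising probes cannot exclude without the sequences, and a change in the lung after silica both stay open.

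Of the 56 other control spots, 4 passed the same limma fit, all of them higher in silica. Among the tested probes 14.4% passed, but that share is no baseline for spike-in and corner spots, which are not expected to follow the treatment. Over the 56 spots the differences ran from -0.31 to 0.81, and the dark corner differed by 0.44 (limma adjusted p = 0.403). Some of these exceed 0.29, the smallest change called among the tested probes, so the control spots were not all level between the groups. These 4 spots also separated the groups fully, which 38.4% of the tested probes did and chance gives for 10%. They were DCP_22_6 (0.38), ERCC-00144_60 (0.49), ETG08_142674 (0.81) and ETG10_13482 (0.66). All except DCP_22_6 had group means below the mean dark corner of the group, 2.73 in saline and 3.17 in silica.

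Saline replicate 1 stood apart from the other saline arrays, with a limma array weight of 0.34, against 1.08 and 2.04 for saline replicates 2 and 3, and bright E1A probes 0.14 to 1.18 above their mean. A wrong group label is argued against, as its lowest correlation with a saline array, 0.972, is above its highest with a silica array, 0.965. Its offset from one saline array correlated over probes with the difference of silica from the other by 0.21 on average (0.19 and 0.24), between the bounds set for and against a silica-like change in this rat. A background level shared with the silica arrays (dark corner 3.37, against 2.97 to 3.28 in silica and 2.54 and 2.27 in saline replicates 2 and 3) should lose that correlation among the 10817 bright probes, where it was 0.21 on average but 0.15 and 0.26 singly. These accounts cannot be told apart with 1 such array.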

How the results depend on the processing

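The count of 7391 changed probes stayed within 1.5 times under another quantile normalization, a common median, both filters on dim probes, an offset of 32 and an intensity trend (7388 to 8725). The first 2 hardly move an already quantile-normalized table and test little. The count was 12580 with array weights, 4429 at a 2-fold change with an unadjusted p under 0.05, 3023 at a 2-fold change with an adjusted p under 0.05, and 1309 with the spike-in probes aligned, an alternative added after seeing the data. Both the weights and the spike-ins act on saline replicate 1. It had the lowest weight (0.34), and its bright E1A probes lay a median of 0.51 above the mean of saline replicates 2 and 3. Aligning on them therefore lowered all its values against theirs. Whether this accounts for the 2 counts was not tested separately. The 2-fold minimum removes smaller changes by construction, and the count of 4429 also differs in using an unadjusted p. The count of changed probes ranged from 1914 to 8664 when each array was left out, where fewer arrays leave fewer degrees of freedom. With a replicate block in limma no probe passed (0, against 13081 at an unadjusted p under 0.05). The block also leaves fewer residual degrees of freedom. The values gave no sign that the numbers pair the rats, as deviations of same-numbered arrays correlated by -0.10, 0.022 and -0.061. Each saline array correlated better with another number, but centring within each group favours this where the same-number value is low. With 3 arrays per group, pairing cannot be excluded. Custom probes changed less often than catalogue probes under every setting that called any. At a 2-fold change with an unadjusted p under 0.05, 49.4% of the changed probes were higher in silica, against 54.5%. No named probe changed direction under any setting that tested it (the stricter filter on dim probes left out both named falls), but the offset of 32 made the log2 differences smaller, from 7.998 to 6.71 for A_44_P491796, from 6.55 to 3.64 for A_44_P309097, from -3.51 to -1.25 for A_44_P669819 and from -3.34 to -1.70 for A_44_P1090877. The rises of A_44_P491796 and A_44_P309097 and of the rat GAPDH probes lost their call only under the block, and those of the rat PGK1 probes also with the spike-ins aligned. Both named falls lost theirs under the block and without single arrays, and that of A_44_P1090877 also with the offset of 32 (adjusted p = 0.0777 in limma). The planned gene, noncoding and gene list results were not run, for want of gene names. Weak signal limits the rest, since the median standard error was 0.29 for probes with a mean under 3, 0.42 for those of 3 to 4 and 0.12 for those of 8 to 10, and values under 3 lie near the floor of the scale.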

Other observations

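The tests in this part were chosen after the results were seen. The 6 probes that rose among the 10 in the separate custom series were bright in all rats, and 4 of them rose by over 2-fold. Brightness did not set them apart, as CUST_R2H_0001, CUST_R2H_0002 and CUST_R2H_0007 did not pass with saline means of 11.35, 14.06 and 15.65. Among all tested probes with a mean over 10, 29.8% changed.

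Custom probes with consecutive numbers changed alike. Over 20826 such pairs the log2 differences between silica and saline correlated by 0.12, above the highest of 1000 shuffled orders (0.022, a permutation p of 0.001, the smallest they can give). The correlation was 0.039 at a distance of 2 numbers and 0.0083 at 3. Both members changed in 438 pairs, against 262 for independent members, and 342 of these went the same way. A candidate explanation is that probe numbers follow transcript or location, so that neighbours in number read one RNA or one locus. A position effect shared by consecutive probes within arrays would also appear among arrays of one group, where the correlation was 0.024. The hypothesis was found and tested on the same data, and the targets of these probes would settle it.

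For the split into silica and saline, no other of the 10 splits of the 6 arrays into 3 and 3 called any probe in limma. The real split was the 1 with 7391, and the highest other gave 0, with 902 to 3608 probes at an unadjusted p under 0.05. As 10 splits allow no share under 0.1, they are too few for a test at 0.05. Every other split also mixes silica and saline arrays in both groups. The difference between silica and saline then adds to the residual spread, so few calls were likely in advance. The 0 calls are therefore no evidence on the real split.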
